A study of Drosophila melanogaster with 2 samples.

How the data were processed

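Chromatin was immunoprecipitated with an antibody against green fluorescent protein from whole pupae of transgenic Drosophila melanogaster, aged 1 day. They expressed a fusion of CG12605 with enhanced green fluorescent protein. CG12605 encodes a zinc finger protein of the Snail and Scratch family. Per the labels, the chromatin was sheared by sonication to fragments of a stated size range, and the 2 libraries are biological replicates of a single group. There is no second condition, so no comparison between groups was made.

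The deposited data used here are 8 peak lists on the dm6 assembly. Per the text deposited with each sample, the authors aligned the reads to dm6, called peaks against a control alignment and ranked them by the irreproducible discovery rate (IDR), which measures how well a peak's rank repeats between a pair of peak calls. The aligner, the peak caller and their versions are not given in the sources used here. For each replicate the authors deposited a ranked and a thresholded list. For the series there are 2 ranked and 2 thresholded lists, derived from the alignments of both replicates. The conservative list was matched to the ranked list that holds every one of its peaks with the same position and signal. The other pair is called series-level here, and what its paired peaks were called on is not given in the sources used here. Each thresholded list was checked to hold peaks of its own ranked list at an IDR of at most 0.01. Per the deposited text, the thresholded lists have a further input file, which was not analysed here.

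The signal value of each peak is the authors' own, deposited with the peak, and its scaling is not given in the sources used here. It served to rank and describe peaks within a list. The integer score deposited by the authors equals 125 times the log2 of 1/IDR, capped at 1000, so it holds the reproducibility of a peak and not its height. The series-level ranked lists also hold 4 signal columns for the members of each pair. These carry no sample names and were only looked at to check that the ranked list of the conservative peaks pairs the 2 replicates. No printed value rests on them, and the replicates' signals come from their own lists. The control alignment, read counts and coverage tracks were not analysed here. The depth of each library is therefore unknown, and the intervals given for shares of peaks cover counting error only.

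The conservative list of 6776 peaks is the main list. Summits were placed on the Ensembl 115 gene annotation and the Release 6 assembly, which has dm6 coordinates. All peaks on the main arms X, 2L, 2R, 3L, 3R and 4 end within the lengths of that assembly. Positions are given counting from 1. The annotation holds 13945 protein-coding genes on these arms, and a gene was called bound when a summit lay within 1000 bp of any of its annotated transcription start sites. The gene nearest to a summit is the one with the nearest start site, which need not be the gene that is regulated. Start sites are those of protein-coding genes throughout, and intergenic means outside these genes, so noncoding genes may lie there. Random placements drew 1000 sets of positions from the sequenced bases of the same arm. The smallest p they can give is 0.000999.

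Motifs were counted on both strands in the 101 bp around each summit and in a window of the same peak centred 300 bp away, on a side chosen at random, and compared with an exact McNemar test over a family of 22 motifs. Of these, 10 were 6-base E-boxes, the short sequences read by Scratch, Snail and bHLH proteins. The family also held sites of other factors and core promoter sequences, such as GAGAG and TATAAA. All 6-base sequences were searched in the same way. The 21 gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Peaks per chromosome arm were compared with the arm's share of the assembled bases by an exact binomial test. Relations of signal with place or sequence were tested by permutation with 100000 resamples. Peaks are not independent replicates, so these tests describe the peak lists and not the spread between animals.

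The main tests, the gene lists, the motifs and all alternatives not named as later additions were chosen before the data were examined. The genes named by rule are the 25 with the strongest peaks within 1000 bp of a start site, the Snail and Scratch family bound or not, and up to 4 genes of each list with the highest promoter signal. The 5 strongest peaks farther than 1000 bp from any protein-coding start site are named too. Delta was matched under its full name. Cpr, a P450 reductase caught by the prefix of the cuticle proteins, was removed from their list, and 1 entry of the list of Hox and appendage factors matched no gene. Alternatives covered the peak list, each replicate alone, distance limits, window sizes, the background sequence, gene sets matched on gene length and number of start sites, and the overlap rule.

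Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The procedures were tested on simulated data. None of 20 sets of 6776 random summits passed 0.05 for the start-site share. With 25% of the summits moved to start sites, the share found was 33.3% where 32.9% was put in. All 60 implanted copies of CAACAGGTG were found, which checks only the counting. Random sets of bound genes gave any called list in 9 of 200 runs. A ribosomal list of 92 genes bound at 60% passed a fixed limit on the unadjusted p in 200 of 200. Bound genes were drawn independently in these runs, so effects of shared peaks, gene length and number of start sites are not covered.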

Results

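The data describe where CG12605-eGFP was found on chromatin in whole pupae, in 2 biological replicates immunoprecipitated with an anti-GFP antibody. The conservative list held 6776 peaks on dm6, with a median width of 360 bp, and covered 2097 kb. Their signal values ran from 8.83 to 1369, with a median of 85.6. The thresholded list of replicate 1 held 4022 peaks and that of replicate 2 held 5394, or 1.34 times as many. The read depth of either library is unknown, so this difference in number cannot be set against depth.

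The strongest promoter peaks included those of a sugar nucleotide transporter, the catalase gene and a glycolytic enzyme. The highest of all peaks, at a signal value of 1369, had its summit 29 bp upstream of Ugalt, which encodes a UDP-galactose transporter. It lies on X at 2703881, and the gene (FBgn0024994, minus strand) runs from 2701124 to 2703852. The start region of eIF2Bbeta lies within 1000 bp of the same summit. Replicate 1 gave this peak a signal of 719 and replicate 2 a signal of 667, each in its own list.

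Other genes among the top 25 promoter peaks included Cat, the catalase gene, at 1073 (3L, summit 18822925, 321 bp from the start site). PNPase, a polynucleotide phosphorylase, had a signal of 1065 (3R, summit 31404657), and Gapdh2, a glycolytic enzyme, had 1002 (X, summit 15867983, 162 bp from the start site). The mitochondrial ribosomal protein genes mRpS10 and mRpL41 had signals of 976 and 894. CenG1A stood at 1053, Tcs5 at 953, the kinase gene Btk at 807, wech at 804, the glutathione transferase GstT4 at 774, the Elongator subunit Elp5 at 772 and Fkbp14 at 768. The others were CG18549 at 1128, CG13204 at 1119, CG14100 at 1063, hdly at 956, CG7601 at 912, CG4586 at 875, CG3552 at 855, CG43658 at 825, CG1635 at 813, CG9147 at 810.3, CG11309 at 782 and CG5611 at 755.

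All 25 of these peaks overlapped a peak in the thresholded lists of both replicates. Of the 25 summits, 21 lay within 200 bp of the start site and 19 lay upstream of it. At 13 of them the start site of another gene lay within 1000 bp, so the peak cannot be given to 1 gene.

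The 5 strongest peaks farther than 1000 bp from any protein-coding start site reached the same height. The first, on 2L at 6612707 with a signal of 1293, lay in an intron of CG11050, 1020 bp from its start site. The next, on 2R at 22569945 with 1020.5, lay in an intron of dnr1, 7638 bp from the nearest start site, that of CG11362. The other 3 lay outside protein-coding genes: on 2L at 2202408 with 996 (nearest start site CG31668, 3758 bp away), on 3R at 29214440 with 982 (eEF1gamma, 5732 bp) and on 2R at 13035344 with 935 (CG13323, 11912 bp).

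Across the whole list, promoters were the most over-represented place. Of the 6776 summits, 2704 lay within 500 bp of a protein-coding start site, or 39.9% (95% exact binomial interval 38.7 to 41.1), against 11.5% ± 0.372 (SD over 1000 random placements), a ratio of 3.48. The permutation p was 0.000999, the smallest possible. Of these 2704 summits, 1778 (65.8%) lay upstream, and 1826 (67.5%) fell between 200 bp upstream and 100 bp downstream. Introns held 2789 summits (41.2%, against 39.4% of random positions), and intergenic sequence, outside protein-coding genes, held 1092 (16.1% against 30.0%). Untranslated exons held 147 (2.17% against 5.10%) and coding exons 44 (0.649% against 14.1%). Random positions take no account of where chromatin is open, and the control alignment was not analysed here. These shares therefore cannot tell binding by CG12605 from background that gathers at open promoters.

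**Figure D1:**
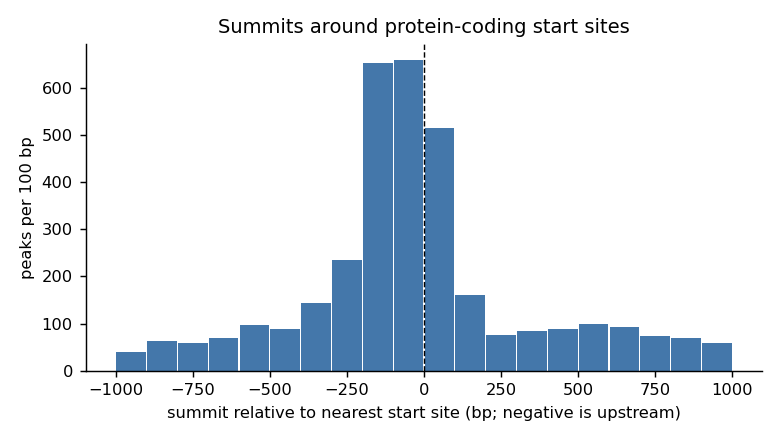
Number of conservative peaks per 100 bp (y axis) by the position of the summit relative to the nearest protein-coding start site in bp (x axis, negative values upstream, dashed line at the start site). The summits crowd just upstream of the start site, with 1826 of them between 200 bp upstream and 100 bp downstream.

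Chromosome 4 was nearly empty of peaks. It held 3 where 67.5 would fall by its length, or 2.25 per megabase (exact binomial test, adjusted p = 1.88e-24); 1 of these lay 183 bp upstream of PlexA, a semaphorin receptor gene. X held 56.5 peaks per megabase and 3L held 54.9, each more than their share (exact binomial test, adjusted p = 4.88e-05 and 0.000756). 3R held 46.6, fewer than its share (exact test, adjusted p = 0.000308), and 2L and 2R, at 49.7 and 49.3, did not pass the test (adjusted p = 0.473 and 0.341). The call for 3R was lost (exact test, adjusted p = 0.107) when 180 peaks that the authors' lists leave out were put back, and in the list of replicate 1 alone 2R was also called lower (27.7 per megabase, adjusted p = 0.0188).

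The replicates shared most of their peaks. Of the 4022 peaks of replicate 1, 3214 (79.9%; 95% exact interval 78.6 to 81.1) overlapped a peak of replicate 2 by at least 1 bp, and 3247 of the 5394 of replicate 2 (60.2%; 58.9 to 61.5) overlapped one of replicate 1. Random placement of the other list gave 2.22% and 1.66% (permutation p = 0.000999 for each, the smallest possible). In the longer ranked lists, 98.5% of replicate 1 peaks and 96.4% of replicate 2 peaks had a partner, where random placement of those lists gave 18.3% and 16.4%. The conservative peaks were also put in 10 groups by signal, with group 1 the strongest. In group 1, 99.6% overlapped a peak in the thresholded lists of both replicates. The share was 50.8% in group 5, 2.06% in group 9 and 23.6% in group 10. Many weaker peaks of the main list are thus not in both of these lists. At 5991 conservative peaks with a summit of both replicates within 100 bp, the signals correlated across peaks with a Spearman coefficient of 0.735 and a Pearson coefficient of 0.846 on the log2 scale. The conservative peaks were kept for ranks that repeat between these replicates, so part of this agreement is built in. Peaks are not independent, and no test across replicates was made.

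Gene groups differed widely in how often their promoters were bound. Of 13945 protein-coding genes, 3223 (23.1%) were bound. Among 21 lists, 7 were bound more often than other genes and 5 less often. Against random gene sets matched on length and number of start sites, 5 lists were called, 2 above and 3 below, and the calls of 8 lists were lost. Of the 74 list members named with their signal, 14 share that peak with the start region of another gene, among them RpS19b, RpS28b, RpL34b, scrib, imd, Ir75c, Or88a and all 4 proteasome genes.

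Genes for the proteins of the cytoplasmic ribosome had the smallest p on the high side, though the share of bound ecdysone response genes was higher. A summit lay at 57 of 92 (62.0%, against 22.9% of other genes; Fisher's exact test, adjusted p = 1.63e-14), where matched random sets gave 19.7 on average (adjusted p = 0.0021, from the smallest unadjusted p these sets can give). The highest signals among the 57 were these: RpL30 had 216, RpS28b 205 and RpL34b 201, and RpS19b had 468, at a summit 900 bp from its start site.

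Notch pathway genes were the other group above both comparisons, with 12 of 26 bound (Fisher's exact test, adjusted p = 0.0193; against matched sets 0.0244). They included the co-repressor gro at 341, the Notch inhibitor numb at 195, the glycosyltransferase fng at 169 and the receptor gene N at 112. The call was lost by the exact test in the series-level thresholded list (adjusted p = 0.0614) and in the stronger part of the list by signal (0.0501).

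Genes of the response to ecdysone, the hormone that drives metamorphosis, were bound at 17 of 26 (Fisher's exact test, adjusted p = 2.7e-05). Among them Eip93F, a regulator of the pupal stage, had a signal of 495 (3R, summit 21972305), Ldh 189.6, Eip75B 169 and Eip74EF 166. Epithelial adhesion and polarity genes were bound at 14 of 23 (exact test, adjusted p = 0.000398), led by scrib at 342, ds at 275, ed at 237 and par-6 at 168. Axon guidance genes were bound at 14 of 27 (exact test, adjusted p = 0.00323), with PlexA at 180.04, Dscam1 at 176, robo2 at 155 and Ten-m at 129.7. Neuroblast and temporal factors were bound at 11 of 22 (exact test, adjusted p = 0.0193), with hb at 640.1, mamo at 544, Syp at 509 and brat at 347. Circadian genes were bound at 6 of 11 (exact test, adjusted p = 0.0413), with sgg at 384, dco at 114, cry at 104 and cyc at 102. Against matched gene sets these 5 lists were not called, with adjusted p of 0.084, 0.166, 0.449, 1.0 and 0.614 for the lists in the order given. The circadian call was also lost by the exact test at 2000 bp (adjusted p = 0.143), over gene bodies (0.0647) and without replicate 2 (0.131), and the neuroblast call in the stronger part of the list by signal (0.0539).

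In 5 lists fewer promoters were bound than among other genes. Chemosensory receptors and odorant binding proteins were bound at 8 of 230 (3.48%; Fisher's exact test, adjusted p = 1.78e-15; against matched sets 0.0021), among them Ir75c at 117, Or88a at 113, Obp56a at 91.0 and Obp99b at 87.3. Replication histone genes were bound at 0 of 111 (exact test, adjusted p = 1.9e-12, and 0.0042 against matched sets). Both tests count these multi-copy genes as independent, which copies need not be, so neither p can be taken at face value. Whether reads could be placed on single copies was not tested. Cuticle and pigmentation genes were bound at 7 of 96 (exact test, adjusted p = 0.000318), with Cpr62Ba at 123, Cpr72Eb at 78.5, Cpr51A at 69.9 and ple at 64.6. Digestive enzymes were bound at 1 of 35, Mal-A5 at 342 (exact test, adjusted p = 0.00526), and proteasome genes at 4 of 48 (adjusted p = 0.0285), with Rpn3 at 102, Rpn13 at 94.4, Prosbeta5 at 89.4 and Rpn8 at 10.3. Against 10000 matched random gene sets, cuticle, digestive and proteasome genes were not called (permutation test, adjusted p = 0.084, 0.28 and 0.228). By the exact test, digestive and proteasome genes were also not called in the stronger part of the list by signal (adjusted p = 0.142 and 0.235) or without replicate 2 (0.0652 and 0.0561), nor were proteasome genes at 2000 bp (0.136).

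Genes of neuron function were bound at 7 of 35, which was not called against other genes (Fisher's exact test, adjusted p = 0.841) but lay below matched sets, which gave 16.4 (adjusted p = 0.00525). The bound members included elav at 410.1, CadN at 289, Dscam1 at 176 and Sh at 139.8. The remaining lists passed neither test, the Snail and Scratch family among them. Immune genes were called higher at 2000 bp (exact test, adjusted p = 0.0144) but not at 1000 bp. The others were immune genes at 9 of 25 (imd 299, cact 236, AttA 158, Myd88 107), Hox and appendage factors at 6 of 24 (Dll 362, salr 196, sd 108, bi 74.2), muscle at 7 of 27 (sls 147, Mef2 109, mys 101, Zasp52 98.8), fat body at 5 of 17 (Lpin 694, Ilp6 89.6, bmm 88.1, Lsd-2 83.8), hemocyte and matrix genes at 4 of 15 (LanA 162, srp 107, trol 83.3, LanB1 81.5), proneural factors at 4 of 16 (emc 167, Fer3 73.0, hry 67.0, da 64.3) and sensory organ factors at 3 of 17 (ct 299.7, ush 207, ttk 100.2).

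**Figure D2:**
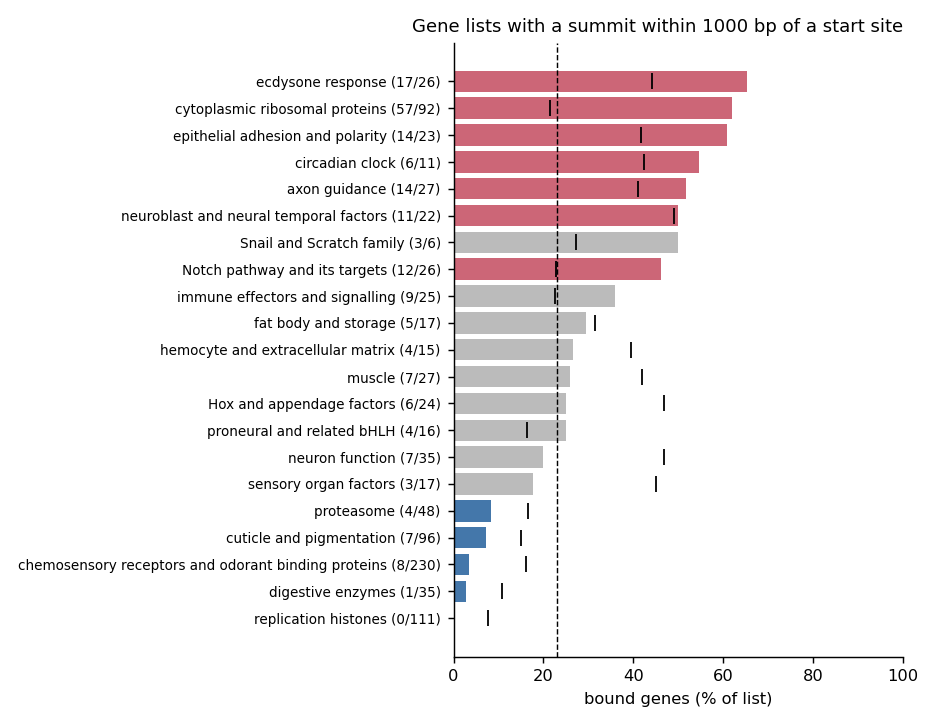
Percentage of each of the 21 gene lists with a summit within 1000 bp of a start site (bars; bound and total genes in parentheses), with red bars above and blue bars below other genes at an adjusted p under 0.05 and grey bars not called; replication histones, at 0, show no bar. The dashed line marks the 23.1% of all protein-coding genes, and the short black ticks the mean of 10000 matched gene sets; cytoplasmic ribosomal proteins (57 of 92) lie above both.

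In the Snail and Scratch family, 3 of 6 genes were bound: CG12605 itself, Kah with a signal of 204 and esg with 65.0. The family was not called against other genes (Fisher's exact test, adjusted p = 0.227) or matched sets (adjusted p = 0.503). No conservative summit lay within 1000 bp of a start site of scrt, sna or wor. At CG12605 (FBgn0035481, 3L 3954251 to 3964771, minus strand), a peak with a signal of 232 had its summit at 3965307, 536 bp upstream, and another of 122 lay inside the gene at 3964133, 156 bp from a start site. The higher of them exceeded 91.4% of all conservative peaks. Replicate 1 gave it 88.5 and replicate 2 gave it 154. The gene with 20 kb on either side held 6 peaks where 2.77 would fall by length (exact binomial test, p = 0.0627). The other peaks there were nearest to CG14984 (187), CG10863 (113), CG12766 (89.7) and Eip63F-1 (53.7). In the ranked list the same region held 40 peaks where 17.7 would fall (exact binomial test, p = 3.85e-06). Most peaks of that list do not meet the IDR limit and some overlap each other, so they are not independent trials. The labels call the flies transgenic but do not say whether the tag is on an added copy of the gene, which would add reads there.

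**Figure D3:**
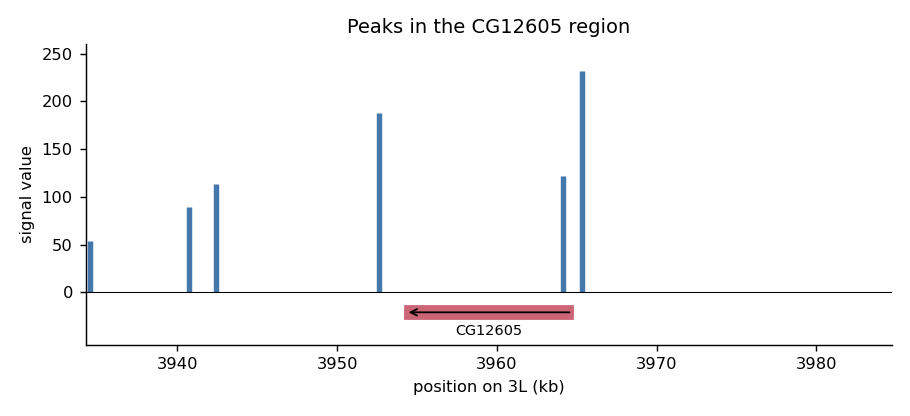
Signal value (y axis) of the 6 conservative peaks in the CG12605 gene and 20 kb on either side, at their summits on 3L in kb (x axis). The red box is the gene, with an arrow in the direction of transcription; the highest peak (232) lies 536 bp upstream of its start site.

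Of 22 motifs, 3 were more frequent at summits than in flanks and 9 less frequent, but against dinucleotide shuffles of the summit sequence 13 were more frequent and 3 less. GGTCACACT and TATCGATA, core promoter sequences, were not called against flanks (log2 ratio 0.67 and 0.45) but were called higher in 5 and 3 of the 10 alternatives. The 9-base E-box CAACAGGTG was present in 59 windows of 101 bp and in 7 flanking windows (log2 ratio 2.99; exact McNemar test, adjusted p = 1.75e-10). It is the sequence bound by Scratch proteins, and 0.871% of the summit windows held it. The genes nearest to the 5 strongest such peaks were CG12278 at 725 (3R, summit 21043762), CG14715 at 378, the nuclear receptor gene Hr4 at 324, the neuropeptide gene AstC at 292 and CNMaR at 285, a choice made after their values were seen. Their start sites lay 306, 4062, 6780, 826 and 158 bp from the summit, in that order. The shorter core CACCTG was not called between summits (221) and flanks (215; exact test, adjusted p = 0.977). CAACAGGTG contains this core on the other strand, so these counts include the 59 and 7 windows above. The core outside those windows was not tested. Of the 10 short E-boxes, 6 were less frequent at summits than in flanks and 0 were more frequent, but against shuffled summit sequence 6 were more frequent and 0 less, so the direction for the short E-boxes rests on the background.

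Other sequences were more common. GAGAG, the site of GAGA factor, occurred in 1326 summit windows and 965 flanks (log2 ratio 0.46; exact test, adjusted p = 1.84e-15), but in peaks farther than 1000 bp from a start site it was not called (adjusted p = 0.209). TATAAA occurred in 1140 and 800 (log2 ratio 0.51; exact test, adjusted p = 1.98e-15), with a log2 ratio of 0.17 against dinucleotide shuffles and 0.93 in peaks farther than 1000 bp from a start site. AGGTCA, a nuclear receptor site, was less frequent, at 100 against 170 (log2 ratio -0.76; exact test, adjusted p = 9.25e-05). In the search over all 2080 sequences of 6 bases, 302 were more frequent at summits and 636 less. Among the more frequent, AAAAAA (2177 against 1396 windows) had the smallest p. Against dinucleotide shuffles 316 were more frequent and 532 less, and the smallest p among the more frequent was that of AGAGAG (761 against 335).

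Summits were poor in GC, and the strongest most of all. GC averaged 38.3% over 101 bp at the summit, against 42.6% in flanking windows. It was 32.7% ± 9.78 (SD, n = 678) in the 678 strongest peaks and 43.4% ± 10.2 (SD, n = 677) in the 677 weakest, and signal and GC correlated across peaks (Spearman -0.258, permutation p = 1e-05, the smallest possible). Peaks with CAACAGGTG had a GC content of 50.7% and a higher median signal than others (107 against 85.4; permutation test, adjusted p = 0.0152), a call lost with the signal of replicate 1 (adjusted p = 0.0661). CAACAGGTG was present in 8 of the 678 strongest peaks, 3 of the 677 weakest and 0 of the top 25 promoter peaks. Peaks with GAGAG had a lower median signal than others (81.8 against 86.5; permutation test, adjusted p = 0.00805), a call lost with the signal of replicate 2 (adjusted p = 0.0731). Peaks within 1000 bp of a start site were not called different in signal from the rest (median 86.8 against 84.6; permutation test, adjusted p = 0.073), but were higher by the signal of replicate 1 (adjusted p = 0.00763).

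**Figure D4:**
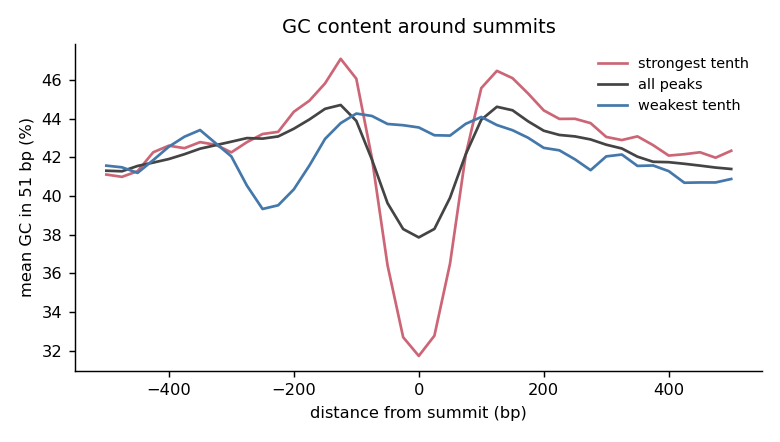
Mean GC content in windows of 51 bp (y axis, %) by distance from the summit in bp (x axis) for all 6776 conservative peaks and for the 678 strongest and 677 weakest by signal; the y axis does not start at 0. GC at the summit averages 31.7% in the strongest peaks, and the weakest peaks show no such dip at the summit but a shallower dip to its left.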

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

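Of the tests below, those of the share near start sites were chosen only after the result was seen. Each ranked list holds peaks that meet the authors' IDR limit but are missing from the matching thresholded list: 181 for the conservative list, 180 for the series-level list, 118 for replicate 1 and 153 for replicate 2. They drew attention because they are reproducible signal outside the lists compared in the main results. Why they were left out is not given in the sources used here.

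Of the 181 peaks, 114 lay on 3R and 43 on 2L, and those on the main arms fell in 66 regions when gaps of up to 20 kb were bridged. Of these regions, 21 held a single missing peak, 15 held 4 or more, and 64 held 0 kept peaks. Each region runs only from its first to its last missing peak. A region with a single missing peak is that peak alone, so a lack of kept peaks there says little. The region at tara, on 3R from 16223729 to 16253219, held 14 missing peaks and 0 kept ones. That at InR, the insulin receptor gene, and E2f1, from 21605276 to 21633901, held 10 missing and 3 kept. By nearest start site, the strongest missing peaks were those of cbt (signal 895, 2L summit 481104, 1416 bp away), Lk6 (885, 970 bp), larp (813, 339 bp), puc (678, 7 bp) and spen (525, 7583 bp). Putting them back made 80 further genes bound, among them Hr39, cwo, Rfx, Syx1A, Tm1 and RpL13A of the fixed lists.

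Repeated sequence, background placed without regard to genes and the further input file of the thresholded lists are each a candidate explanation, and the tables argue against the former 2. Of the 180 missing summits on the main arms, 0.556% had a 51 bp sequence that occurs again there, against 0 of 180 kept peaks drawn at random (Fisher's exact p = 1.0). Within 500 bp of a start site lay 45.0%, against at most 20.6% in 1000 placements of single peaks and, since peaks of a region are not independent, at most 22.2% in 1000 placements of whole regions. Exclusion by the further input file stays open, as does background that gathers at open promoters, since neither that file nor the control alignment was analysed here. No biological explanation was tested.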

How the results depend on the processing

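Alternatives chosen only after seeing the data are the lists with the missing peaks put back, signal agreement over other pairs, and leaving out peaks that overlap a stronger one. The share near start sites kept its direction and call in all 8 alternatives (32.1% to 50.5%), as did CAACAGGTG in all 10 (log2 ratio 1.85 to 4.09). The number of called gene lists was 12, and 8 to 12 in the alternatives except matched gene sets, which gave 5; the cause was not tested. Overlap moved with its rule, for peaks of replicate 1 and replicate 2: 67.9% and 50.6% with 50% of each peak shared, 76.1% and 56.8% with summits within 100 bp, 72.6% and 71.0% with lists of equal length, and 85.4% and 63.7% in the stronger part of each list. Signal agreement (Spearman) was 0.772 for summits within 50 bp and 0.748 over all ranked peaks. The log2 difference in signal at promoters was 0.073 with replicate 1, where it was called. Motifs called in the main comparison or the alternative changed sign (log2 ratios) against dinucleotide shuffles (CAAATG 0.20, CAACTG 0.36, CAAGTG 0.50, CACATG 0.058, CAGCTG 0.85, CGATAG 0.67, TTAATTA -0.43, GTAAACA 0.47) and flanks at 1000 bp (CAAGTG 0.039, CACCTG -0.35), and CAAATG ranged from -0.14 to 0.055 when either replicate was left out; the cause was not tested. Of the other comparisons of single motifs, 159 stayed on their side of the threshold (32 of them changed sign without a call in either), 24 lost a call and 16 gained one. Of single gene lists, 168 stayed (18 changed sign without a call), 19 lost a call and 2 gained one. Read depth is unknown, so what it limits cannot be stated.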

Other observations

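Of the tests below, the comparison of ribosomal protein genes with proteasome and tRNA genes, the counts near noncoding genes, and the first test on signalling genes were chosen only after the result was seen. Genes for tRNAs and for the class annotated as ncRNA lay near summits more often than random placement gives. A conservative summit lay within 250 bp of the start of 49 of 290 tRNA genes (16.9%), against a mean of 7.13 and at most 19 over 1000 placements (permutation test, adjusted p = 0.003). tRNA genes are clustered, and 35 peaks account for the 49; 18 of these peaks lay farther than 1000 bp from a protein-coding start site, and their median signal over all 35 was 73.8. Of 3261 ncRNA genes, 158 had a summit (permutation test, adjusted p = 0.003, with a mean of 81.3 in random placements). Random placement ignores the crowding of summits at protein-coding start sites, and how many of the 158 lie there was not counted. The other classes were not called: snoRNA at 11 of 269 and snRNA at 2 of 32 (permutation test, adjusted p = 0.325 for each), rRNA at 0 of 99 and pseudogenes at 4 of 268 (permutation test, adjusted p = 0.34 for each).

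Of 1381 copies of CAACAGGTG on the main arms, 88 (6.37%) lay in a conservative peak. The 59 summit windows with it held 61 copies.

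The high share of bound ribosomal protein promoters may reflect gene structure, or reads collected at highly transcribed genes of any kind. Matched gene sets argue against the former as the whole source (permutation test over 10000 sets, adjusted p = 0.0021). The latter cannot be told apart from specific binding. Proteasome promoters were bound at 8.33%, below other genes but not called against matched sets (permutation test, adjusted p = 0.228), while tRNA genes were bound above random positions. Whether all genes of the proteasome list are highly transcribed in these pupae is unknown, since expression was not analysed here. No biological explanation was tested.

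That stronger peaks have AT-richer summits might come from GC bias of the libraries, from 1 library, or from weak peaks called beside a stronger one. The tables argue against the latter 2 as the whole source. From the weakest to the strongest peaks, GC at the summit fell by 11.8 percentage points, but at 150 bp from it the fall was -2.78 (SE 0.439), which is a rise. GC bias was predicted to give a fall there of at least 5.90 points, which was not found. Fragments span both places, and GC over whole fragments was not compared, so GC bias stays open. Signal and GC correlated at -0.277 in the list of replicate 1 and at -0.246 in that of replicate 2. Without the 396 peaks that overlap a stronger peak, among them 53.2% of the 677 weakest, the correlation was -0.23. The fall at the summit was then 9.62 points (SE 0.65), and that at 150 bp was -2.46 (SE 0.45). No biological explanation was tested.

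Of those 396 peaks, 382 had the stronger peak at the lower coordinate and 14 at the higher. Without them, 39.9% of 6380 summits lay within 500 bp of a start site.

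A hypothesis that CAACAGGTG marks peaks near signalling genes was not borne out. It arose from reading the names of the genes nearest to such peaks, and words for receptors, channels, neuropeptides, hormones, synapses and transporters were chosen after those names had been read. On these same genes, 9 of 58 carried a word against 100 of 3263 nearest to other peaks (Fisher's exact p = 8.8e-05), which is no evidence, since the words were chosen with the genes in view. Among genes not looked at before, nearest to peaks past the IDR limit, 3 of 104 carried a word (2.88%) against 305 of 8365 (3.65%; Fisher's exact p = 1.0). Those peaks are less reproducible, so a relation limited to the conservative peaks was not tested independently.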
